A study of Mus musculus with 5 samples.

How the data were processed

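RNA sequencing of mouse liver tumours was analysed from 1 deposited table of 22287 genes, with 2 wild-type (WT) and 3 lnc-CTHCC knockout (KO) libraries. Total RNA was extracted with Trizol and sequenced on Illumina libraries, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.0, HISAT2, StringTie, DESeq2 and limma, and the mouse build mm10, without a role or an order for any of them. The gene annotation and the strand setting used by the authors are not given in the sources used here. The values of each library are FPKM (fragments per kilobase of gene, scaled to the fragments of the library) made by the authors, per the file headers, and were rounded to 2 decimals. The deposited table also holds the authors' mean FPKM per genotype, with 0.001 in place of a mean of 0, and the authors' log2 fold change of KO over WT. It further holds the authors' p-value and false discovery rate per gene, per the file headers; the tool behind these p-values is not given in the sources used here. FPKM values carry no library totals and the low values showed no clear step of 1 read, so the depth is unknown and no count model or interval was computed.

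Groups and replicate numbers were taken from the sample titles. The labels do not say that the samples of a genotype came from separate animals, so the p-values may measure only the spread between these samples, which may be technical. The transcript of lnc-CTHCC was not analysed here, and the genotypes were taken as labelled. Gene symbols and Ensembl gene identifiers came from the table, where 28 symbols were listed more than once. Of the 22287 identifiers, 22253 were found in GENCODE vM21, which is built on GRCm38, the same assembly as mm10. Coordinates are 1-based and come from that annotation, in which 21786 of the identifiers are protein-coding genes.

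Values were transformed to log2(FPKM + 1). Genes with a mean FPKM of at least 1 over the 5 libraries were tested, which left 10132 genes, and 6001 genes were listed at 0 in all libraries. KO was compared with WT by limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean-variance trend, two-sided, 3 residual degrees of freedom, no covariate). P-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Fold changes are KO minus WT on the log2(FPKM + 1) scale, which understates the change of low genes. An exact permutation test of 2 against 3 libraries cannot give a two-sided p below 0.1, so none was used for single genes. A simulation used 20 draws on the 10132 genes of this comparison, with the fitted spread and 200 changed genes per draw. It recovered 43.6% of 2-fold and 97.2% of 4-fold changes, which were set on the log2(FPKM + 1) scale. Genes varied independently of each other in it, and with fewer changed genes the threshold would be stricter. The shares recovered may therefore be lower in these data.

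The test, its samples, the alternatives, 47 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 5 members tested, 42 of them, were tested by limma's camera with a preset correlation of 0.01 between genes, adjusted over the 42 lists. Camera with the correlation estimated from the data and fry, a rotation test of whether a list's genes move on balance one way, were run beside it. For each list the members past the threshold were counted over all genes tested and adjusted over the list alone. The genes named in the text were Yap1, Ccn1, Ccn2, Ankrd1, Hnrnpk, Afp, Gpc3, Mki67 and Alb whatever their values. To these were added up to 12 genes per direction past the threshold whose WT and KO values did not overlap, leaving out predicted or clone-named genes. Each direction was filled to 8 by the smallest unadjusted p among genes without overlap, of which 1 is not reported here. Up to 4 members per list by the smallest unadjusted p were added, as were sex chromosome transcripts and markers of other tissues. Other names were chosen after their values were seen, and are said to be so.

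The alternatives were pseudocounts of 0.1 and 5, no expression filter, a mean FPKM of at least 5, rescaling to a common sum, median-ratio rescaling, quantile normalization, no trend, robust empirical Bayes, the replicate number as a block and leaving out each library. Rescaling without Alb, array weights, median-ratio rescaling with the block, and the estimated correlation with median-ratio rescaling, with no expression filter or with rescaling to a common sum were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.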

Results

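The transcriptome of liver tumours was measured by RNA sequencing in C57BL/6 mice treated with DEN, a liver carcinogen, and CCl4, a liver toxicant, for 5 months. Tumours came from 2 wild-type (WT) and 3 lnc-CTHCC knockout (KO) samples, lnc-CTHCC being a long non-coding RNA. The FPKM values of a library summed to between 526229 (KO 1) and 552619 (WT 1), and its depth is unknown. Alb, the gene of serum albumin, took 17.1% of the sum in WT 1, 14.1% in WT 2 and 14.6% to 15.6% in the KO libraries. The 10 most abundant genes took 41.9% in WT 1 and 33.4% in WT 2. Across genes, the lowest correlation between any pair of libraries was that of WT 1 with WT 2 (r = 0.965), and the highest was that of KO 1 with KO 2 (r = 0.984). The first principal component, with 43.9% of the variance, set WT 1 (-23.8) apart from WT 2 (27.3), with the KO libraries between them. On the second, with 24.4%, WT 1 (-15.2) and WT 2 (-11.5) lay below KO 1 (20.1), KO 2 (6.03) and KO 3 (0.633).

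The comparison of KO with WT asks which transcripts of the tumour differ when lnc-CTHCC is lost. Onecut1, a homeobox transcription factor of hepatocytes (also called HNF6), rose in KO tumours. It was at 2.29 ± 0.134 FPKM (SD, n = 2) in WT and 11.1 ± 1.31 FPKM (SD, n = 3) in KO tumours, a ratio of 4.82. Serpina6, which encodes corticosteroid-binding globulin, had the next smallest p-value among genes with higher values in KO, but did not pass the test. Sult2a2, a hydroxysteroid sulfotransferase, and Vil1, the actin-bundling protein villin, led the genes with lower values in KO and did not pass it either.

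Onecut1 (ENSMUSG00000043013, chromosome 9, 74861921 to 74891781, plus strand) was the only gene of 10132 past the threshold, with a log2 difference of 1.87 (SE 0.188, limma adjusted p = 0.047), and was above both WT libraries in all 3 KO libraries. No gene was lower past the threshold. By limma, 327 genes had an unadjusted p under 0.05, of which 180 were higher and 147 lower in KO, where 506.6 would be reached if no gene changed. The values of the genotypes did not overlap in 15.1% of the genes tested, where chance gives 20%. The Onecut1 call was lost without WT 2 (adjusted p = 0.0974), KO 1 (0.224), KO 2 (0.0994) or KO 3 (0.516), and with a pseudocount of 5 (0.0674), no expression filter (0.304), a mean FPKM of at least 5 (0.0669), median-ratio rescaling (0.0819) or quantile normalization (0.12). It was also lost with rescaling without Alb (0.0639) and with array weights (0.139), both added after seeing the data, and its log2 difference stayed between 1.14 and 2.21 in all alternatives.

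The other genes named in the higher group did not pass the test. Serpina6 (chromosome 12, 103646630 to 103657212, minus strand) was at 83.0 ± 8.57 FPKM (SD, n = 2) in WT and 241 ± 40.3 FPKM (SD, n = 3) in KO tumours, with a log2 difference of 1.52 (limma adjusted p = 0.0857). Slc25a30, a mitochondrial carrier, was at 8.69 and 32.5 FPKM (limma adjusted p = 0.22). Kifc3, a kinesin, was at 8.21 and 17.3 FPKM, Enc1 at 4.39 and 9.16, Rab38, a small GTPase, at 0.635 and 1.98, and Epdr1 at 1.39 and 4.93. In each of these 6 genes all 3 KO libraries lay above both WT libraries, which the rule for naming them required.

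Genes of the lower group did not pass the test either. Sult2a2 (chromosome 7, 13733505 to 13779636, plus strand) was at 32.2 ± 3.60 FPKM (SD, n = 2) in WT and 9.45 ± 1.79 FPKM (SD, n = 3) in KO tumours, with a log2 difference of -1.68 (limma adjusted p = 0.0857). Its values are uncertain as far as reads were shared with similar sulfotransferase genes. Vil1 (chromosome 1, 74409376 to 74435559, plus strand) was at 2.20 and 4.59 FPKM in the WT libraries and at 0.30, 0.04 and 0.11 FPKM in the KO libraries (limma adjusted p = 0.111). Car14, a carbonic anhydrase, was at 8.66 and 1.73 FPKM in WT and KO (limma adjusted p = 0.123), and Ciart, a repressor of the circadian clock, at 7.27 and 1.33 FPKM (limma adjusted p = 0.147). Slc51b, a subunit of a bile acid exporter, was at 5.72 and 0.993 FPKM (limma adjusted p = 0.16). Crybb3, a crystallin, was at 3.68 and 0.723 FPKM, Hal, the first enzyme of histidine breakdown, at 52.3 and 20.2, and Slc25a22, a mitochondrial glutamate carrier, at 45.3 and 24.5.

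**Figure D1:**
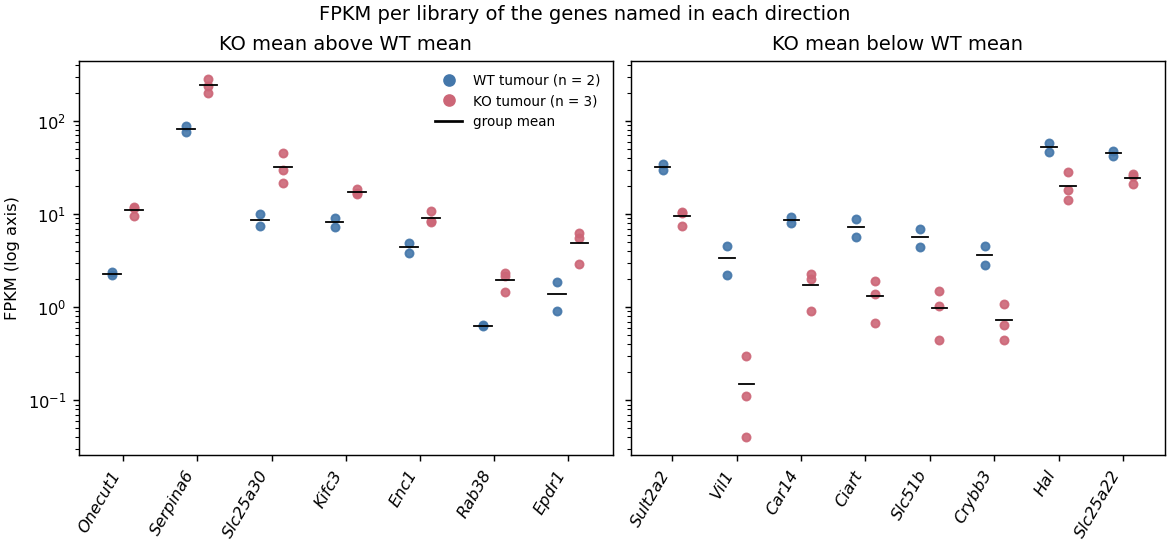
FPKM per library (log axis) of the genes named in the higher (7 genes) and lower (8 genes) groups, for 2 WT and 3 KO tumours; points are libraries and black lines are group means. In Onecut1 the KO libraries sit between 9.57 and 12.04 FPKM and the WT libraries at 2.20 and 2.39 FPKM, and it alone passed the test.

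The authors' deposited table gives a false discovery rate under 0.05 for 36 genes, 8 higher and 28 lower in KO. Of these, 32 were tested here, all with the same sign and all with an unadjusted p under 0.05 by limma, and 4 were below the expression filter. Both results use the same 5 libraries, so this is no independent check, and of the 32 only Onecut1 passed here. In the authors' deposited table the smallest rates belong to Vil1 (1.91e-21) and Onecut1 (1.72e-20). Genes of that table outside the naming rule, chosen after their values were seen, include Inhba, a subunit of activin, with a log2 fold change of 1.13 in the authors' deposited table, and Bcl6, a transcriptional repressor, with -2.10. The chemokines Cxcl9 and Cxcl1 have log2 fold changes of -1.59 and -1.19 in the authors' deposited table.

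Published work on lnc-CTHCC concerns the transcription of YAP1, the effector of the Hippo pathway, so Yap1 and its target genes were compared first among the gene lists. Yap1 was at 13.1 ± 0.636 FPKM (SD, n = 2) in WT and 15.6 ± 1.55 FPKM (SD, n = 3) in KO tumours, with all 3 KO libraries above both WT libraries. Such a lack of overlap, in either direction, was seen in 15.1% of all genes tested, where chance gives 20%. The log2 difference of Yap1 of 0.24 (SE 0.174) did not pass the test (limma adjusted p = 0.999). Of 16 YAP1 target genes tested, 12 had a higher and 4 a lower mean in KO. As a list they rose against the other genes by camera with the preset correlation (mean log2 difference 0.27, adjusted p = 0.00376). The adjusted p was 0.808 with an estimated correlation, and no member passed over all genes or adjusted over the list alone.

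Ccn1 and Ccn2, secreted matricellular proteins, were at 2.42 and 10.2 FPKM in WT and at 5.16 and 15.4 FPKM in KO tumours. Nt5e, the ectoenzyme CD73, had a log2 difference of 0.63, Igfbp3 of 0.59, Amotl2 of 0.51 and Ankrd1 of 0.23. Hippo pathway components rose as a list (17 of 22 higher, mean log2 difference 0.15, camera adjusted p = 0.0441 with the preset correlation), with an adjusted p = 0.808 with an estimated correlation. Amotl2 and Lats2 belong to both lists. No Hippo component passed adjusted over the list alone, and Hnrnpk, an RNA-binding protein, was at 87.6 and 91.5 FPKM. The call of the YAP1 targets was lost without WT 1 (camera adjusted p = 0.0502) or WT 2 (0.0531), and that of the Hippo components without WT 1 or KO 1, where its adjusted p reached 0.365, and with quantile normalization, the replicate block or array weights.

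**Figure D2:**
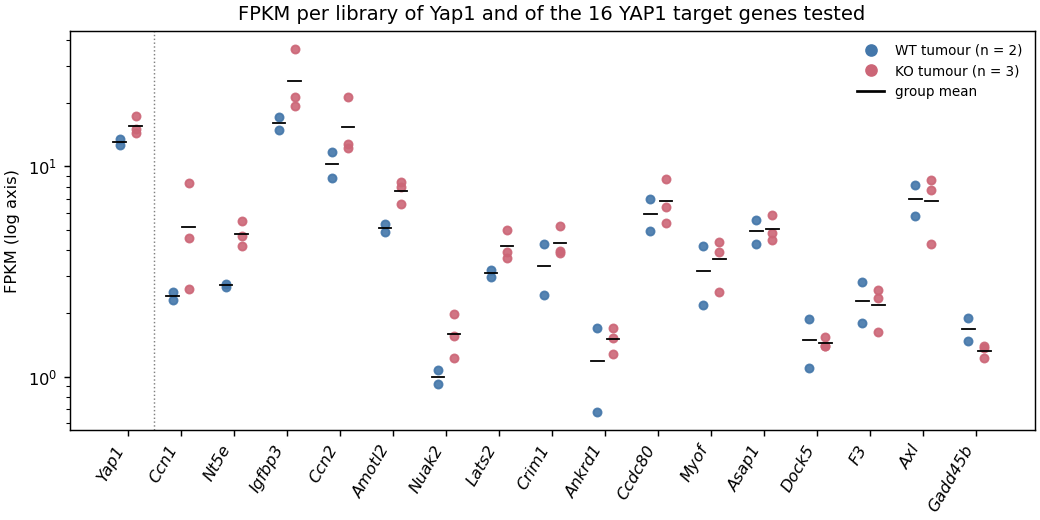
FPKM per library (log axis) of Yap1 (left of the dotted line) and of the 16 YAP1 target genes tested, for 2 WT and 3 KO tumours; points are libraries and black lines are group means. Yap1 lies between 12.61 and 13.51 FPKM in WT and between 14.41 and 17.35 FPKM in KO, a difference that did not pass the test.

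The urea cycle and amino acid catabolism list fell (27 of 30 members lower, mean log2 difference -0.37, camera adjusted p = 8.75e-10 with the preset correlation), and its adjusted p was 0.741 with an estimated correlation. Periportal hepatocyte genes, expressed around the portal vein, fell too (18 of 20 lower, mean -0.48, camera adjusted p = 2.6e-08), with an adjusted p = 0.718 with an estimated correlation. These lists share 8 genes, and without them the remaining 12 periportal genes had a mean of -0.43 (camera adjusted p = 0.00243, and adjusted p = 0.732 with an estimated correlation).

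Adjusted over the list alone, 2 amino acid genes passed, Hal and Sds, the serine dehydratase, and 4 periportal genes, these and Etnppl and Aldh1b1; over all genes tested none did. Sds was at 97.3 and 141 FPKM in the WT libraries and at 26.7, 54.0 and 56.2 FPKM in the KO libraries. Etnppl was at 3.34 and 19.9 FPKM in WT and at 1.33, 1.32 and 1.5 FPKM in KO. Without WT 2 the amino acid call was lost (camera adjusted p = 0.0616) and the mean log2 difference of that list was 0.02, against -0.76 without WT 1 and -0.22 without KO 1. The periportal mean was -0.27 without WT 2, and the median of all genes tested was then 0.16, against 0.05 with all libraries.

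Bile acid synthesis and transport genes fell (14 of 21 lower, mean -0.12, camera adjusted p = 0.0337), with an adjusted p = 0.808 with an estimated correlation. Among them, Abcb11, the canalicular bile salt exporter, had a log2 difference of -0.92. Hepatocyte transcription factors rose (15 of 20 higher, mean 0.25, camera adjusted p = 0.0337), with an adjusted p = 0.718 with an estimated correlation. Onecut1 was the member past the threshold over all genes and adjusted over the list alone. Foxa1, Foxa2 and Cebpa, which did not pass, had log2 differences of 0.82, 0.87 and 0.63. By fry, this list was the 1 of 42 called for change in either direction (adjusted p = 0.047). It was not tested without Onecut1, which may carry that call. The bile acid call was lost without WT 2, KO 1 or KO 2, and that of the transcription factors without WT 2 or KO 2. Without WT 2 the bile acid mean was 0.22, where the median of all genes tested was 0.16. Both calls were lost after median-ratio rescaling, and the bile acid call also with no expression filter or quantile normalization.

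Cell cycle and mitosis genes fell in KO tumours as a list (13 of 15 tested lower, mean log2 difference -0.31, camera adjusted p = 1.11e-08 with the preset correlation), with an adjusted p = 0.718 with an estimated correlation. Members had low values, with Ube2c at 5.06 and 5.98 FPKM in WT and 3.42 to 3.92 FPKM in KO, and Birc5 at 2.05 and 3.98 FPKM in WT and 1.19 to 1.67 FPKM in KO. No member passed over all genes or adjusted over the list alone, and the list mean was -0.16 without WT 2. Mki67, the proliferation marker Ki-67, was below the expression filter at 0.69 and 1.68 FPKM in WT and 0.93, 0.58 and 0.84 FPKM in KO. The DNA replication list did not pass (camera adjusted p = 0.055). Afp, alpha-fetoprotein, a tumour marker, was at 191 and 71.5 FPKM in the WT libraries and at 163, 67.6 and 59.5 FPKM in the KO libraries, so without WT 1 the KO mean of 96.7 FPKM lies above WT. Gpc3, glypican 3, another, was at 101 and 97.8 FPKM in WT and at 190, 129 and 94.1 FPKM in KO, and neither passed the test.

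B and plasma cell markers fell as a list (9 of 10 tested lower, mean log2 difference -0.79, camera adjusted p = 1.99e-08), with an adjusted p = 0.718 with an estimated correlation. Igha, the IgA heavy chain, was at 81.5 and 248 FPKM in the WT libraries and at 44.6, 58.5 and 12.3 FPKM in the KO libraries. Igkc, the kappa light chain, was at 71.9 and 175 FPKM in WT and at 49.6, 56.1 and 19.5 FPKM in KO. Adjusted over the list alone, 6 members passed as lower and 1 as higher, Xbp1 (189 and 261 FPKM), which hepatocytes also express, and over all genes tested none did. The list mean was -0.43 without WT 2. Of T and NK cell markers, 2 passed the expression filter, too few to test as a list. With no expression filter, 32 of 33 had a lower mean in KO, most of them with means under 1 FPKM (mean log2 difference -0.23, camera adjusted p = 4.68e-16 with the preset correlation, and adjusted p = 0.797 with an estimated correlation), and the list mean was -0.30 to -0.15 with 1 library left out. After rescaling to a common sum, 6 of them passed the filter (mean -0.59, camera adjusted p = 2.35e-07 with the preset correlation, and adjusted p = 0.649 with an estimated correlation).

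Acute phase genes fell (21 of 25 lower, mean -0.50, camera adjusted p = 1.99e-08), with an adjusted p = 0.739 with an estimated correlation. Lcn2, lipocalin 2, was at 849 and 1144 FPKM in WT and at 403, 669 and 432 FPKM in KO, and Orm2, an orosomucoid, at 17.7 and 103.5 FPKM in WT and 3.81, 6.35 and 13.8 FPKM in KO. Inflammatory cytokines and NF-kB targets (8 of 13 lower, camera adjusted p = 0.0417) and dendritic cell and antigen presentation genes (12 of 16 lower, camera adjusted p = 0.00529) fell, with adjusted p = 0.808 and 0.739 with an estimated correlation. Cxcl1 passed adjusted over the list alone, and no acute phase or antigen presentation member did. Without WT 2 the mean log2 difference was -0.04 for acute phase, 0.08 for inflammatory and -0.01 for antigen presentation genes, against -0.50, -0.14 and -0.17 with all libraries. The median of all genes tested was then 0.16, against 0.05 with all libraries. The inflammatory call was lost without WT 2 or KO 1 (camera adjusted p up to 0.464), with a mean FPKM of at least 5 and after median-ratio rescaling, and that of antigen presentation without WT 2 (0.11) and with a mean FPKM of at least 5.

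**Figure D3:**
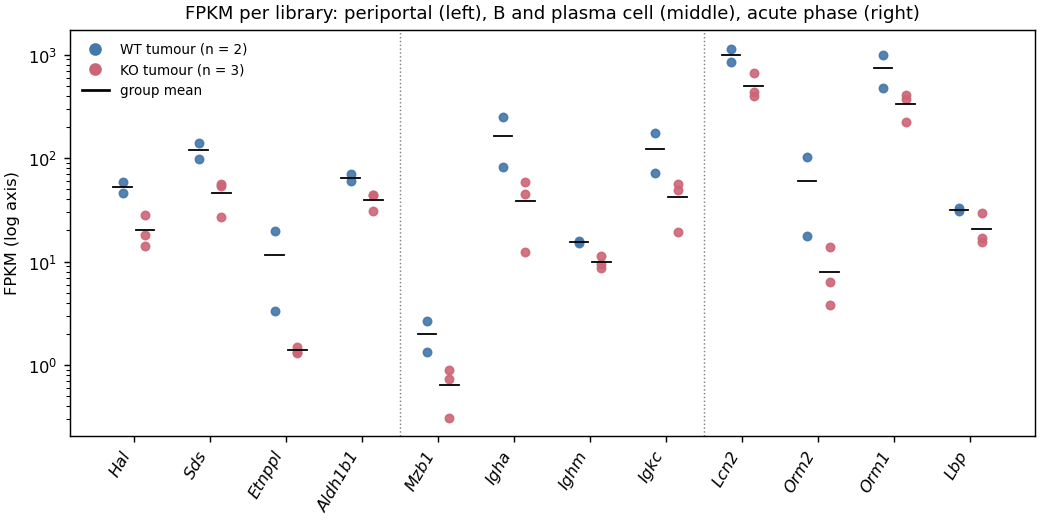
FPKM per library (log axis) of the 4 periportal (left), B and plasma cell (middle) and acute phase (right) genes with the smallest p, for 2 WT and 3 KO tumours; points are libraries and black lines are group means. WT 2 lies highest in several of them, such as Igha (248 FPKM against 81.5 FPKM in WT 1).

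Mitochondrially encoded genes fell (12 of 13 lower, mean log2 difference -0.23, camera adjusted p = 4.16e-06), with an adjusted p = 0.741 with an estimated correlation. They took 11.5% and 13.2% of the FPKM sum in the WT libraries and 10.1%, 10.1% and 11.3% in the KO libraries. Nuclear genes of oxidative phosphorylation fell by less (23 of 27 lower, mean -0.09, camera adjusted p = 0.00295), with an adjusted p = 0.808 with an estimated correlation. Male-biased liver genes (11 of 14 lower, mean -0.26, camera adjusted p = 0.00376) and NRF2 antioxidant genes (15 of 26 lower, mean -0.07, camera adjusted p = 0.0489) fell, both with an adjusted p = 0.808 with an estimated correlation. Growth factor signalling genes rose (17 of 24 higher, mean 0.21, camera adjusted p = 0.0413), with an adjusted p = 0.718 with an estimated correlation. No member of these 5 lists passed adjusted over the list alone; Egfr, the receptor of epidermal growth factor, and Myc had log2 differences of 0.54 and 0.82. Calls were lost without WT 2 or KO 1 for oxidative phosphorylation (camera adjusted p up to 0.297), WT 2 or KO 2 for male-biased genes (up to 0.91), WT 1, KO 1 or KO 3 for NRF2 genes (up to 0.951) and WT 2 or KO 3 for growth factor genes (up to 0.282). NRF2 genes also lost the call with a pseudocount of 5, no expression filter, median-ratio rescaling, quantile normalization, no trend, the replicate block or array weights, and growth factor genes with a mean FPKM of at least 5 or median-ratio rescaling. The tested direction turned for NRF2 genes without WT 1 (camera adjusted p = 0.794) and with the replicate block (0.623), and for growth factor genes without WT 2 (0.282). Without WT 2 the mean was -0.14 for mitochondrially encoded, 0.01 for oxidative phosphorylation and 0.23 for male-biased genes, where the median of all genes tested was 0.16.

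Of the 42 lists tested, 16 passed with the preset correlation, 4 higher and 12 lower. Splits of the 5 libraries that mix the genotypes called up to 22 lists in that way. For KO against WT, none passed with an estimated correlation, where 0 lists had an unadjusted p under 0.05 and the smallest adjusted p was 0.718. By fry, none passed for a move on balance one way (smallest adjusted p = 0.804). Among lists that did not pass, markers of endothelial cells (camera adjusted p = 0.0657), macrophages and Kupffer cells (0.618), stellate cells and fibroblasts (0.822), cholangiocytes (0.822), neutrophils (0.379) and erythroid cells (0.822) stood beside hepatocyte secreted proteins (0.235). In 4 lists, the liver tumour, neutrophil, female-biased and circadian lists, the mean and the median differed in sign. The Y-linked genes Ddx3y (3.97 to 10.57 FPKM), Eif2s3y (6.29 to 12.12 FPKM), Kdm5d and Uty were expressed in all 5 libraries. Of the markers of other tissues, all but Cela1, Msln and Upk3b were under 1 FPKM in every library, and Ins2, Adipoq and Plin1, of pancreas and fat, were listed at 0. Cela1, a pancreatic elastase, was at 26.9 and 18.8 FPKM in the WT libraries and at 16.9, 14.4 and 17.8 FPKM in the KO libraries. The mesothelial marker Msln was at 1.29 and 1.93 FPKM in WT and at 3.5, 3.18 and 1.14 FPKM in KO, and Upk3b, also mesothelial, at 0.51 and 0.78 FPKM in WT and at 1.74, 1.66 and 0.55 FPKM in KO; none of the 3 passed the test.

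**Figure D4:**
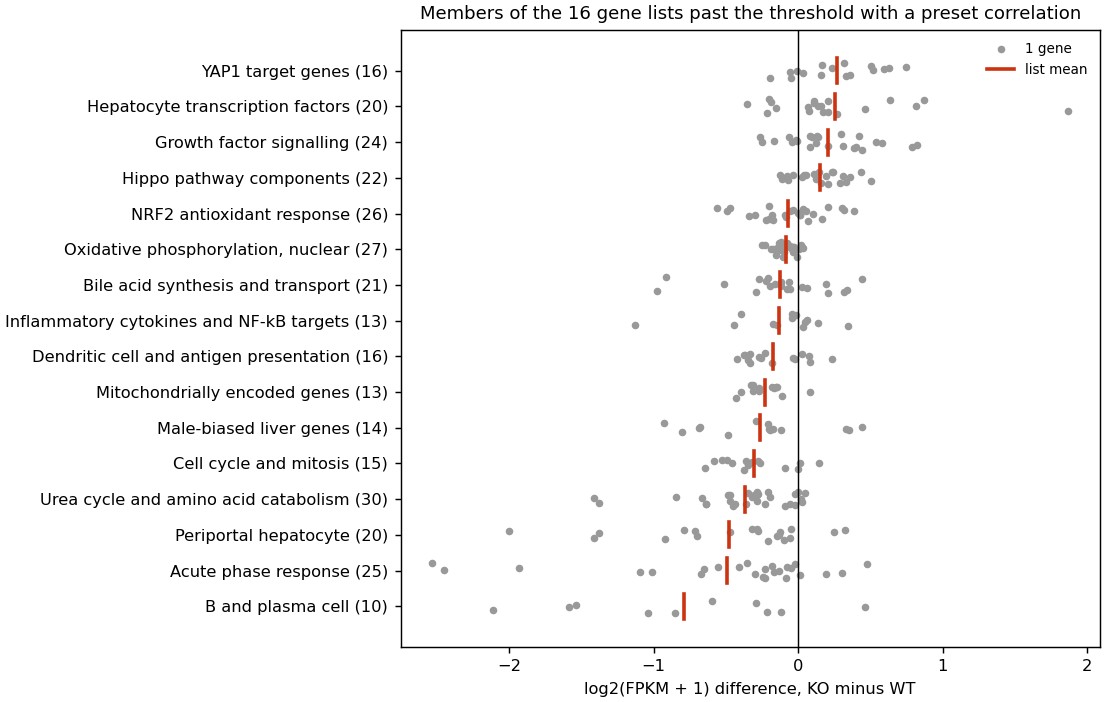
Log2(FPKM + 1) difference, KO minus WT, of the members (grey points) of the 16 gene lists past the threshold with the preset correlation; red lines are list means and numbers in brackets are genes tested. List means run from -0.79 for B and plasma cell markers to 0.27 for YAP1 targets, and none of the lists passed with an estimated correlation.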

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

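Rescaling without Alb, array weights and all settings that combine 2 choices were chosen only after the results were seen. Of genes, limma called 1 with pseudocount 0.1, rescaling to a common sum or no trend, Onecut1 each time. It called 0 with pseudocount 5, no expression filter, a mean FPKM of at least 5, median-ratio rescaling, quantile normalization, rescaling without Alb and array weights, where 311, 676, 167, 409, 428, 320 and 204 genes had an unadjusted p under 0.05. It called 3 with robust empirical Bayes, which were Onecut1, Serpina6 and Sult2a2. Leaving out 1 library gave 0 to 17 genes: 17 without WT 1, 1 (Akr1b7, not Onecut1) without WT 2, and 0 without KO 1, KO 2 or KO 3, where 196, 296 and 286 had an unadjusted p under 0.05. Where 1 WT library was left, it was assumed to vary like the KO libraries. The cause of these shifts was not tested. With the replicate block, 62 genes (19 higher, 43 lower) and 26 lists were called, and 55 genes after median-ratio rescaling with the block. The numbers are shared by only 2 pairs, whose deviations correlated at 0.0884 and -0.24 across genes. With 2 WT libraries their deviations mirror each other, so this check shows neither pairing nor its absence, and the labels do not say that a number marks a shared litter or day. Of lists, 0 were called with the estimated correlation, by fry, and with the estimated correlation after median-ratio rescaling, with no expression filter or after rescaling to a common sum, where the YAP1 target list had adjusted p = 0.808, 0.902, 0.673, 0.797 and 0.821. Other settings called 11 to 20 lists and leaving out 1 library 12 to 22, and none called any of the 16 lists in the other direction. Without WT 2, the mean of the amino acid list was 0.02. The adjusted p of the YAP1 targets was 0.0013 to 0.0531 when 1 library was left out. Of 3318 pairs of a named gene and a setting, 32 changed sign, none of a called gene, 52 passed the threshold anew and 11 lost it. FPKM gives no depth, so what depth limits is unknown.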

Other observations

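Tests of the clock genes and of the growth hormone genes were fixed before their values were seen; the tests on splits, scaling, feeding state and non-hepatocyte cells, and the choice of patterns, came only after the result was seen.

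Ciart and Car14, both lower in KO tumours without passing the test, lie close to each other on chromosome 3. Ciart lies at 95878503 to 95882251 and Car14 at 95897768 to 95904691, both on the minus strand and 15516 bases apart. Within 100 kb of the pair, 8 other genes were tested, and their log2 differences ran from -0.22 to 0.09, none with an unadjusted p under 0.05 by limma. One of these, BC028528, lies between Ciart and Car14 on the same strand, and was at 1.08 FPKM in WT and 1.07 FPKM in KO. Aph1a overlaps the end of Car14 on the opposite strand, and was at 21.8 FPKM in WT and 18.5 FPKM in KO. This pair was noticed after its values were seen.

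Outside the B and plasma cell list, 7 immunoglobulin genes were tested, looked up after the list result was seen. All 7 had a lower mean in KO, with a median log2 difference of -0.98, and in 2 of them all 3 KO libraries lay below both WT libraries. In 5 of the 7 the KO mean was also below WT 1, the lower WT library. None passed the test over all genes, and reads shared between these similar genes leave single values uncertain.

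The lower B and plasma cell list was set against a loss of non-hepatocyte cells of every type from the KO pieces. Such a loss would lower the stellate cell, endothelial and macrophage lists by about as much, but these differed from the B and plasma cell list by 0.91 on the log2 scale (SE 0.425), being higher in KO by 0.12 (SE 0.199). That is little more than 2 standard errors, which with 3 residual degrees of freedom is too little to decide against such a loss as the whole cause. The B and plasma cell mean was -0.79 with all libraries and -0.43 without WT 2, and the T and NK cell list, tested with no expression filter, had a mean of -0.23 (camera adjusted p = 4.68e-16 with the preset correlation, but adjusted p = 0.797 with an estimated correlation), which a loss of every type would lower too. A loss of every type and fewer lymphocytes in the KO tumours, by genotype or by the piece sampled, may all remain, and no test here separates these.

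The lower amino acid catabolism list was set against the scaling of the libraries and against feeding state. After median-ratio rescaling the list still passed (camera adjusted p = 4.56e-07 with the preset correlation, but adjusted p = 0.832 with an estimated correlation, against 0.741 before rescaling). Its mean was -0.43 after rescaling and -0.37 before, while the median of all genes tested went from 0.051 to 0.0025. Such rescaling moves most genes of a library together, and camera compares the list with the other genes. A call this strong could thus hardly change, so the test does not decide about scaling. Feeding-induced minus fasting-induced genes outside the list differed by -0.27 (SE 0.302) between KO and WT, where a fed state in KO would make it positive. The difference was not positive, but with 3 residual degrees of freedom its standard error is too large to decide against a fed KO state. The mean of the amino acid list was -0.76 without WT 1 and 0.02 without WT 2, so its size rests on WT 2, and an effect of genotype and a peculiarity of that library may both stay open.

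The lower Ciart was set against the time of day at which tumours were collected. Its clock output partners Dbp, Tef, Hlf, Nr1d1, Nr1d2 and Per3, minus the tested genes of the Arntl arm, differed by -0.70 (SE 0.384) between KO and WT. This lies neither beyond 2 standard errors nor within the bound set for no shift, so a shift in collection time and an effect of genotype cannot be told apart. Nr1d1 was at 26.4 and 6.54 FPKM in the WT libraries and at 5.01, 8.24 and 4.46 FPKM in the KO libraries.

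A hypothesis of stronger growth hormone signalling in KO tumours came from Onecut1, Cish and Socs2, which are growth hormone induced, and Bcl6, which growth hormone represses. Cish was at 2.98 and 1.18 FPKM in the WT libraries and at 12.4, 10.6 and 3.78 FPKM in the KO libraries, and Socs2 at 6.37 and 3.29 FPKM in WT and 11.3, 8.72 and 13.6 FPKM in KO. Bcl6 was at 1.67 and 6.47 FPKM in WT and at 1.03, 0.70 and 1.11 FPKM in KO, so the size of its difference rests on WT 2; of the 4 genes only Onecut1 passed the test. Igf1, Igfals, Gadd45g and Pim3 had a mean log2 difference of 0.096 (SE 0.331), which neither shows nor excludes the shift of 0.5 set in advance. The single differences were 0.40 for Igf1, 0.45 for Gadd45g, -0.013 for Igfals and -0.45 for Pim3. Pim3 was lower in all 3 KO libraries than in both WT libraries, and the higher Igf1 mean rested on KO 3 (165 FPKM). The test leaves the hypothesis open.

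The 10 splits of the 5 libraries into 2 and 3 are too few for a share under 0.05. The real split called 1 gene and the highest other 4, with 3 splits calling at least 1; the real split called 16 lists with the preset correlation and the highest other 22, with 8 splits calling at least 16. With an estimated correlation, 0 lists were called in each of the 10 splits. The numbers of genes and lists called thus did not set the genotype split apart from splits that mix the genotypes.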
